A study of Oryza sativa with 12 samples.

How the data were processed

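RNA was measured in stem bases of 8-day-old rice seedlings (Oryza sativa, cultivar Taichung 65) on the Affymetrix Rice Genome Array. The 12 arrays fall into 6 groups of 2: wild type and crl1, each just before and 2 h and 4 h after indole-3-acetic acid was added to a final 1e-06 M. Each extract came from 20 stem bases. Per the labels, the deposited values are linear intensities, 1 MAS5 signal per probe set, made by the authors in Affymetrix Expression Console, with no version stated. The values themselves show the authors' scaling: the mean signal after trimming 2% of probe sets at each end was 100 on every array. No detection calls and no raw image files were used here.

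The table holds 57381 probe sets, of which 57194 are rice probe sets, 123 are Affymetrix controls and 64 are reporter probe sets of genes that rice lacks. The platform annotation pairs 22531 probe sets with genes, 22436 of them with exactly 1 gene, and leaves 34663 rice probe sets without a gene. The gene table (assembly ASM3414082v1, used for names only) held all 17905 genes of these probe sets, of which 2446 have a name other than a LOC number. Genes are given by name and LOC identifier, since a name such as IAA20 belongs to more than 1 gene. A search of the synonyms in that table for ARL1, the name searched for CRL1, and for CRL5 found 0 entries. CRL4 was not searched for by name. The levels of CRL1, CRL4 and CRL5 were not analysed here.

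Signals were turned to log2 with no further scaling. Rice probe sets above the median of all rice probe sets of the same array on at least 2 of the 12 arrays were kept, which left 32524 probe sets and 16438 genes. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with 1 mean per group, which leaves 6 residual degrees of freedom and a median prior of 4.79. The comparisons were crl1 against wild type before auxin, at 2 h, at 4 h and averaged over the 3 times, 2 h and 4 h against 0 h in each genotype, and the difference of the responses of the genotypes at 2 h and at 4 h. P-values were adjusted over all kept probe sets by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold, and all tests were two-sided. Errors printed beside log2 fold changes are standard errors from this model, which rests on 2 arrays per group, and the number of arrays limits their precision.

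The 95th percentile of the 64 reporter probe sets on each array, 5.83 to 18.5, served as background. Where both arrays of a group lay at or below it, the fold change was also computed against the background and is given as "at least". A log2 fold change printed for such a gene without "at least" is the model's value for the deposited signals and not a bound.

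Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with 1 probe set per gene, and adjusted over 28 lists and the main comparisons together (280 tests). 52 tests passed 0.05 at the preset correlation and 0 passed with a correlation estimated from the residuals, so each list call is printed with that second adjusted p. 24 lists were fixed before the data were examined, as were the model, the filter, the threshold and the rule for naming genes. Their wording relied on gene descriptions and RAP locus identifiers. The gene table has no descriptions, and 0 of the 78 RAP identifiers were found in it, so the lists were translated to gene symbols once the names had been read, before any groups were compared. At that point 8 lists were added: kinesins, phosphate and ammonium transporters, iron and zinc uptake, diterpenoid phytoalexin synthesis, aquaporins, DREB and late embryogenesis proteins, cellulose synthases of primary walls, and homeodomain-leucine zipper factors. The lists for ethylene synthesis and gibberellin oxidases (2 measured genes each) and for LBD factors and SAUR genes (1 each) held too few measured genes to test. For each list the number of members past the threshold is given over all probe sets and adjusted over the list alone.

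Genes were named by a fixed rule. In each comparison it took genes past the threshold that had a name of their own and whose arrays did not overlap between the groups (for a difference of responses, whose order was the same in each repetition), and from these the 10 largest rises and the 10 largest falls, with 1 probe set per gene, the brightest. It further took up to 4 members of each list past the threshold over all probe sets, and WOX11, WOX9 (also called QHB), RR1 and RR2 whatever their p. Genes named as past adjusted over the list alone, and genes given by a LOC number only, lie outside the rule and were chosen after their values were seen.

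The series describes 2 independent repetitions, and the labels number the arrays by repetition. Deviations of the arrays from their group means correlated above 0.1 in 11 of the 15 pairs of groups, from 0.00776 to 0.249 over all kept probe sets and from -0.056 to 0.561 over bright ones, so the fit with repetition as a block is given beside results that it moved. The step was tested on simulated data in which 100 probe sets were changed 2-fold and 100 4-fold. Of the changes, 4% of the 2-fold and 61% of the 4-fold ones were recovered for crl1 against wild type before auxin, 50% and 83% for that comparison over all times, 1% and 53% for wild type at 2 h against 0 h, and 2% and 19% for the difference of responses at 2 h, each over 32524 probe sets. Of the calls in these 4 tests 4 of 69, 10 of 143, 9 of 63 and 3 of 24 fell on unchanged probe sets, a higher share than the threshold of 0.05 in each. Noise in these tests was drawn independently for each array, without deviations shared within a repetition. A simulated shift of 0.5 log2 units in 1 list of 28 was recovered. Genes in that simulation were drawn independently, so it did not test the list calls under correlation between genes.

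The fixed alternatives were quantile normalization, centring each array on its median, no filter, a filter at the 75th percentile, a pseudocount, eBayes without the trend, repetition as a block, a fit of the compared groups alone, a 2-fold minimum, each array left out in turn, and an estimated correlation for the lists. Array weights, the GAPDH 3' to 5' ratio as a covariate, a repetition block within each genotype, list tests without the array of wild type at 2 h, repetition 2, both kinds of list test with an estimated correlation, genes chosen by the response of crl1 and the responses averaged over both genotypes were added after seeing the data.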

Results

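Transcripts of the rice stem base, the part of the seedling where crown roots form, were compared between wild type and crown rootless 1 (crl1), a mutant that lacks crown roots. Each genotype was sampled at 0 h and at 2 h and 4 h after auxin (indole-3-acetic acid, 1e-06 M), with 2 arrays in each of the 6 groups and 12 in all. The number of arrays limits the precision of every value below. Median signals of the rice probe sets ran from 9.39 to 12.7, and 42.8% to 57% of rice probe sets lay above background. Arrays of plants kept to 2 h or 4 h without auxin were not analysed here, so each change with time holds both the auxin and the hours that passed.

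One array stood apart. Wild type 2 h repetition 2 had a hybridisation control signal of 1404 against 421 to 671 on the other 11 arrays, a poly-A control signal of 388 against 45.6 to 155 and a GAPDH 3' to 5' ratio of 35.6 against 3.08 to 17.3. Its 18S rRNA signal was 556 against 3399 to 5290. Its mean correlation with the other arrays, across probe sets that are not independent replicates, was 0.904 against 0.935 to 0.949. The 2 arrays of wild type 2 h differed with an SD of 0.795 log2 units, and those of the other groups with 0.379 to 0.543. Results that rest on this array are given with their value without it. In a fit without wild type 2 h repetition 1 this array is alone in its group, and its distance from repetition 1 no longer counts as spread. High counts from that fit cannot be told apart from the deviation of this array.

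**Figure D1:**
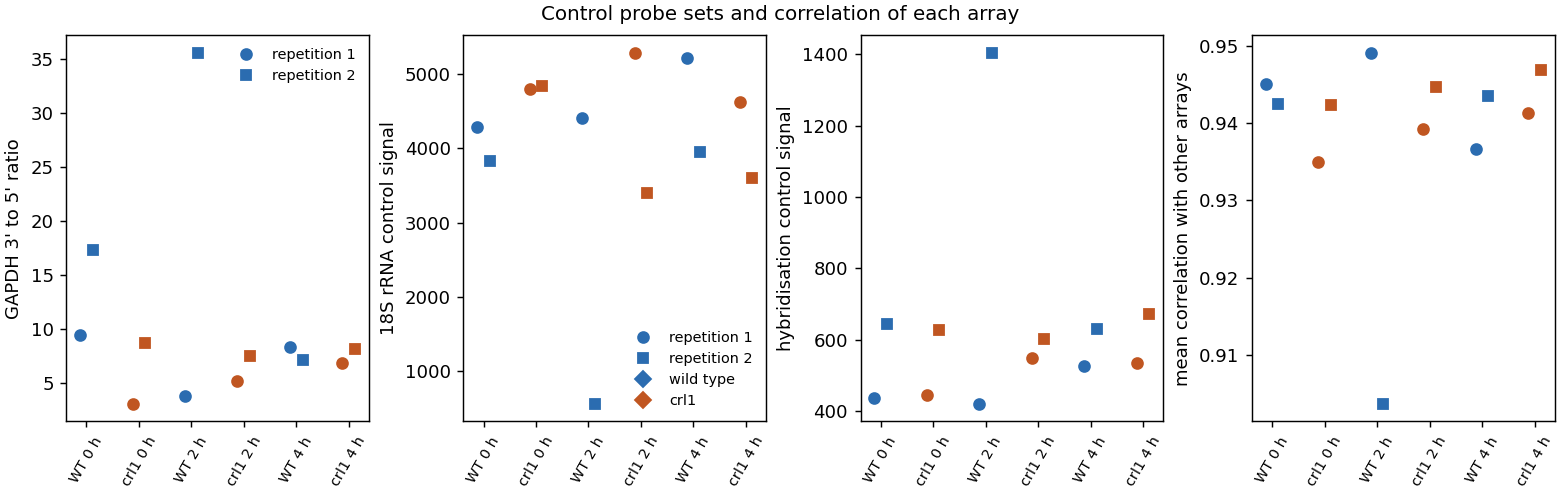
GAPDH 3' to 5' signal ratio, 18S rRNA control signal, hybridisation control signal (MAS5 units) and mean correlation with the other 11 arrays, 1 point per array, with wild type in blue, crl1 in orange, repetition 1 as circles and repetition 2 as squares. Wild type 2 h repetition 2 lies outside the other arrays in all 4 panels, with a ratio of 35.6, an 18S signal of 556, a control signal of 1404 and a mean correlation of 0.904.

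The first comparison asked how crl1 differed from wild type before auxin. AGGLUTININ (LOC4335068), named for a carbohydrate-binding lectin, was lower in crl1 by -6.74 ± 0.66 log2 units (SE, n = 2 arrays per group; limma adjusted p = 0.0032), with signals of 1966 and 1986 in wild type and 15.4 and 22.2 in crl1. LOX3 (LOC4333818), a lipoxygenase, was at least 8.6-fold lower (-3.58 ± 0.50), and PIN2 (LOC4341736), an auxin efflux carrier, at least 3.17-fold lower (-2.80 ± 0.39), as crl1 signals of both lay at or below background. RAA1 (LOC4326229), a gene of root architecture, and IPA1 (LOC4345998), a transcription factor of shoot architecture, were lower by -2.26 ± 0.32 and -2.20 ± 0.30, and for all 4 genes the adjusted p was 0.027. In each of these 5 genes both wild-type arrays lay above both crl1 arrays.

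Before auxin 33 probe sets passed the test, 8 of them of no single gene and the others of 23 genes, 4 higher and 29 lower in crl1, and 71 did with repetition as a block (10 higher, 61 lower). With each array centred on its median 34 passed, 1 higher and 33 lower. Those higher in the main fit included LOC4325628 (1.57 ± 0.22, adjusted p = 0.027), chosen after its values were seen, and 3 probe sets with no gene. None of the members named in advance passed: WOX11 was at -0.07 ± 0.26 (adjusted p = 0.96), WOX9 at -1.32 ± 0.56 (0.53, crl1 at or below background), RR1 at 0.10 ± 0.42 (0.96) and RR2 at -0.29 ± 0.31 (0.81). With limma's camera 0 of 28 lists passed, and 5 did at an unadjusted p under 0.05. With the GAPDH 3' to 5' ratio of each array as a covariate 7 lists passed, among them ribosomal proteins (median 0.37 instead of 0.11, adjusted p = 4.2e-09), aquaporins (0.39 instead of 0.15, 0.0019), histones (0.42 instead of 0.12, 0.0037) and the clock list (-0.48 instead of -0.37, 0.032). With the covariate and an estimated correlation 0 passed (lowest adjusted p = 0.53). Ribosomal proteins were at 0.037 without wild type 2 h repetition 2 (adjusted p = 0.82 with an estimated correlation). The nearest were the ribosomal proteins, with 18 of 23 genes above 0 (adjusted p = 0.066; adjusted p = 0.82 with an estimated correlation), and the class III peroxidases, with 3 of 3 above 0 and a median of 1.92 (adjusted p = 0.095; adjusted p = 0.66 with an estimated correlation). The count was 0 and 7 without wild type 0 h repetition 1 and 2, and 9 without crl1 0 h repetition 1. It was 50 without wild type 2 h repetition 2, and 18 and 19 without wild type 4 h repetition 1 and 2 and likewise without crl1 4 h repetition 1 and 2. AGGLUTININ missed the threshold without wild type 0 h repetition 1 (0.065) or 2 (0.057) or crl1 0 h repetition 1 (0.063). LOX3, PIN2, RAA1 and IPA1 passed in 4, 4, 3 and 6 of the 12 fits with 1 array left out. The highest adjusted p was 0.3 without wild type 0 h repetition 2 for LOX3, PIN2 and RAA1 and 0.26 without repetition 1 for IPA1.

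At 2 h after auxin the same contrast asked how the genotypes differed once auxin was present. AGGLUTININ remained lower in crl1 (-7.14 ± 0.66, n = 2 arrays per group, adjusted p = 0.0021) and passed in 12 of the 12 fits with 1 array left out. NAC076 (LOC4341201), a NAC transcription factor, was at least 4.53-fold lower (-6.32 ± 0.87, adjusted p = 0.03), LOX3 at least 5.31-fold lower (-3.50 ± 0.50, 0.036) and IPA1 lower by -2.11 ± 0.30 (0.034), with both wild-type arrays above both crl1 arrays in each. Among gene groups, 22 of 23 cytosolic ribosomal proteins (median -0.40, adjusted p = 5.4e-05), 6 of 6 histones (-0.64, 0.0052) and 30 of 40 cell cycle and DNA replication genes (-0.30, 0.0024) lay lower in crl1, each with adjusted p = 0.66 with an estimated correlation. So did 5 of 5 type-A cytokinin response regulators (-0.41, 0.049; adjusted p = 0.66 with an estimated correlation). The cellulose synthases of primary walls lay higher, 6 of 6, with a median of 0.53 (adjusted p = 0.006; adjusted p = 0.66 with an estimated correlation). No member of these lists passed over all probe sets, and adjusted over the list alone only RR4 among the type-A regulators did (-0.86 ± 0.24, 0.023). Genes named here or below as past adjusted over the list alone, and not over all probe sets, were chosen after their values were seen. Wild type 2 h repetition 2, with its GAPDH ratio of 35.6, moved with these groups. Without it the medians were -0.08 for ribosomal proteins (adjusted p = 0.31), -0.29 for histones (0.12), -0.10 for the cell cycle (0.14) and -0.64 for the type-A regulators. The GH3 genes and expansins, which did not pass in the main fit, had medians of 0.37 and 0.25 without it (0.45 and -0.08 with it). With the GAPDH covariate the medians of ribosomal proteins, histones, the cell cycle and the type-A regulators were -0.23, -0.42, -0.19 and -0.79. After quantile normalization that of ribosomal proteins was -0.25. The type-A call was at 0.069 with repetition as a block.

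Over all probe sets 24 passed at 2 h (5 of no single gene, the others of 18 genes), 4 higher and 20 lower, and 36 with repetition as a block. A fit of the compared groups alone gave 2, array weights 12 and a filter at the 75th percentile 11. LOX3 and IPA1 passed in 5 and 4 of 8 other settings. Of the 4 probe sets higher in the main fit LOC4325628 again passed (2.18 ± 0.22, adjusted p = 0.0032), chosen after its values were seen, with 3 probe sets of no gene. WOX11 was at 0.62 ± 0.26 (adjusted p = 0.43), WOX9 at -0.76 ± 0.56 (0.6), RR1 at -1.0 ± 0.42 (0.43) and RR2 at -0.21 ± 0.31 (0.81). Without wild type 2 h repetition 1 the count was 4761, and without repetition 2 it was 12, with 11 of the 24 among them. Without crl1 2 h repetition 1 it was 11, and without either array of wild type 0 h, crl1 0 h or crl1 4 h it was 15. NAC076, LOX3 and IPA1 passed in 4, 2 and 1 of the 12 fits with 1 array left out. Their adjusted p was 0.24, 0.23 and 0.12 without wild type 2 h repetition 2, and at the highest 0.27, 0.33 and 0.36 without crl1 2 h repetition 1.

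At 4 h AGGLUTININ (-6.17 ± 0.66, n = 2 arrays per group, adjusted p = 0.0054) and LOX3 (at least 7.89-fold, -3.33 ± 0.50, 0.048) were lower in crl1, with no overlap between the arrays of the genotypes. The cell wall groups lay higher in crl1. All 6 of 6 cellulose synthases of primary walls were above 0 (median 0.71, camera adjusted p = 0.00016; adjusted p = 0.66 with an estimated correlation). Of them 5, among them CESA5 (0.76 ± 0.23) and CESA8 (0.61 ± 0.20), passed adjusted over the list alone. Of 25 expansins and xyloglucan endotransglucosylases, which loosen and rebuild walls, 19 lay above 0 (median 0.43, adjusted p = 0.015; adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone EXPB11 (1.56 ± 0.25), EXP2 (1.14 ± 0.19) and EXP1 (0.78) of these were higher and EXPB18 (-2.77 ± 0.59) was lower, and none passed over all probe sets. Kinesins, the motor proteins of microtubules, were above 0 in 29 of 32 (median 0.51, adjusted p = 3e-05; adjusted p = 0.66 with an estimated correlation). No kinesin passed over all probe sets or adjusted over the list alone. The photosynthesis genes lay below 0 in 7 of 7 (median -0.35, adjusted p = 0.006; adjusted p = 0.66 with an estimated correlation) and the type-A cytokinin response regulators in 4 of 5 (-0.47, 0.022; adjusted p = 0.66 with an estimated correlation). Adjusted over the list alone 1 gene of each was lower, RBCS, the small subunit of Rubisco (-1.14 ± 0.22), and RR4 (-0.86 ± 0.24), and none passed over all probe sets.

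Over all probe sets 26 passed at 4 h (9 of no single gene, the others of 16 genes), 9 higher and 17 lower. The higher ones included LOC4328018 (4.15) and LOC4339315 (2.89), chosen after their values were seen. WOX11 was at 0.80 ± 0.26 (adjusted p = 0.51), WOX9 at -0.51 ± 0.56 (0.91), RR1 at 0.25 ± 0.42 (0.95) and RR2 at -0.47 ± 0.31 (0.82). The count was 11 without either wild type 0 h array, 17 without either crl1 0 h array, and 44 and 43 without wild type 2 h repetition 1 and 2. It was 16 and 15 without crl1 2 h repetition 1 and 2, 8 without wild type 4 h repetition 1, and 7 without either crl1 4 h array. AGGLUTININ missed the threshold only without wild type 4 h repetition 1 (0.09), and LOX3 passed in 4 of the 12 fits with 1 array left out, with the highest adjusted p at 0.37 without crl1 4 h repetition 1.

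Averaging the genotype difference over the 3 times asked which genes differed in crl1 whatever the hour, with 6 arrays per genotype. Arrays of the same genotype and repetition shared deviations from their group means (median r = 0.464 over bright probe sets, against 0.193 between genotypes). The 6 arrays of a genotype are therefore not 6 independent units, and the standard errors and adjusted p below may be too small. A block within each genotype was run for changes with time only. The genes lower in crl1 included AGGLUTININ (-6.68 ± 0.38, n = 6 arrays per genotype, adjusted p = 1.3e-05), IPA1 (-1.93 ± 0.17, 0.00039), the auxin-methylating enzyme IAMT1 (LOC4337315, -2.64 ± 0.32, 0.0029) and the expansin EXPB18 (LOC4338206, -2.76 ± 0.34, 0.0033). NAC076 (-5.49 ± 0.50, 0.00047), LOX3 (-3.47 ± 0.29, 0.00025), CSLC3 (LOC4345095, a cellulose synthase-like gene, -2.90 ± 0.41, 0.0073) and PIN2 (-1.79 ± 0.22, 0.0035) were lower too. Signals of IAMT1, EXPB18 and PIN2 lay at or below background in crl1 at 0 h, of PIN2 also at 2 h, and of NAC076, LOX3 and CSLC3 at every time, so these folds cannot be read as bounds. MFT2, a member of the MOTHER OF FT family, was higher by 5.07 ± 0.66 (adjusted p = 0.0045, wild type at or below background at 0 h), and GLU15 (LOC4345463), an endoglucanase, by 1.67 ± 0.24 (0.0079). At each of the times, both arrays of a genotype lay on the same side of both of the other in all of these genes, and each passed in 12 of the 12 fits with 1 array left out. Such a gap was a condition of the rule for the largest changes. The rule also took list members that passed. Among them the expansins EXPB11 (0.72 to 0.93) and EXP2 (0.58 to 0.69) were higher in crl1. RBCS (-0.73 to -0.60), HOX12 (-1.46 to -0.99), IRT1 (-1.78 to -1.33) and RAB16D (-1.51 to -1.12) were lower. These are ranges of log2 fold change with 1 array left out, and none of these genes passed in every such fit. Other genes named for the largest changes passed in fewer of the 12 fits. Lower in crl1 were HOX14 (4 fits), RA5 (6) and LOX1.1 (9). Higher were CIPK6 (10), TUB8 (8), CHT6 (6), GLP2 (5), ILL8 (4), ARF3 (3), BAT1 (2) and CBP3 (2).

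**Figure D2:**
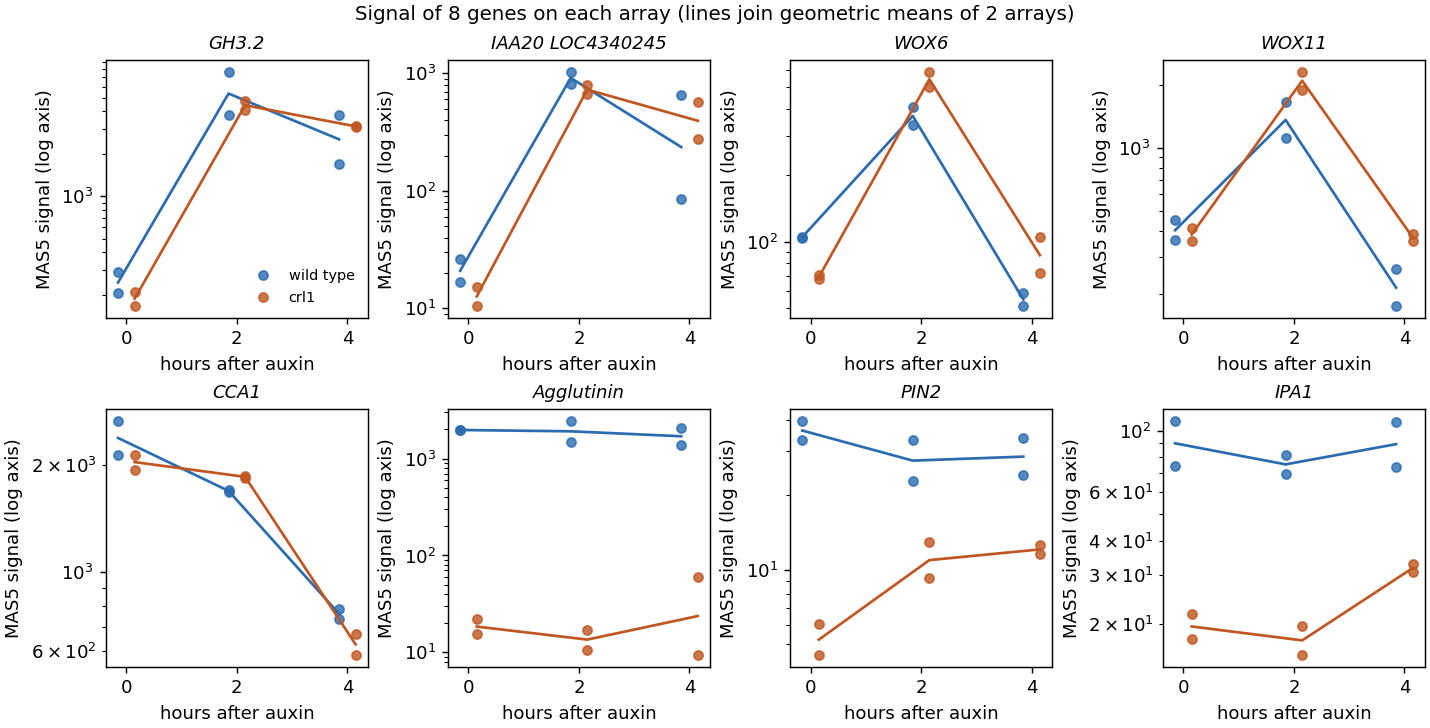
MAS5 signal (log axis) of 8 genes against hours after auxin, 1 point per array, wild type in blue and crl1 in orange, with lines through the geometric means of the 2 arrays of each group. AGGLUTININ, PIN2 and IPA1 lie lower in crl1 at each time, GH3.2, IAA20 LOC4340245, WOX6 and WOX11 lie highest at 2 h in both genotypes, and CCA1 lies lowest at 4 h.

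Hormone genes passed in both directions over all times. ARF3 (LOC4327014, 0.91 ± 0.18, adjusted p = 0.039) and ARF2 (LOC4325895, 0.59 ± 0.11, 0.032), auxin response factors, and CKX4 (LOC4326515, 1.21 ± 0.20, 0.02), which breaks down cytokinin, were higher. The repressor IAA2 (LOC4326775, -0.63 ± 0.13, 0.041), CKX5 (LOC4327887, -0.91 ± 0.19, 0.043) and RR4 (LOC4325747, -0.70 ± 0.14, 0.039) were lower. Of these genes all but CKX4 had arrays of the genotypes apart. These 6 passed in 3, 3, 7, 2, 2 and 2 of the 12 fits with 1 array left out. Their highest adjusted p were 0.13 (ARF3, without crl1 2 h repetition 1), 0.12 (ARF2, crl1 4 h repetition 1), and 0.078 (CKX4, wild type 4 h repetition 1 and crl1 4 h repetition 1). They were 0.15 (IAA2, crl1 4 h repetition 1), 0.14 (CKX5, wild type 0 h repetition 1) and 0.14 (RR4, wild type 0 h repetition 1). The type-A regulators lay below 0 in 5 of 5, 1 of them past the test over all probe sets and 1 adjusted over the list alone (median -0.32, adjusted p = 0.032; adjusted p = 0.66 with an estimated correlation). The primary-wall cellulose synthases lay above 0 in 6 of 6, with 0 past over all probe sets and 5 higher adjusted over the list alone (median 0.43, adjusted p = 8e-04; adjusted p = 0.66 with an estimated correlation). WOX11 was at 0.45 ± 0.15 (adjusted p = 0.17), WOX9 at -0.86 ± 0.32 (0.22), RR1 at -0.22 ± 0.24 (0.69) and RR2 at -0.32 ± 0.18 (0.39).

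Over all times 449 probe sets passed, 142 of them of no single gene and the others of 290 genes, 148 higher and 301 lower in crl1, and 1037 with repetition as a block (394 higher, 643 lower). The share higher was 33%, and 15.5% of 542 with each array centred on its median. At a change of at least 2-fold, 263 passed. The count was 151 and 192 without wild type 0 h repetition 1 and 2, 202 without crl1 0 h repetition 1, and 3675 without wild type 2 h repetition 1. It was 169 and 218 without crl1 2 h repetition 1 and 2, 165 and 283 without wild type 4 h repetition 1 and 2, and 163 and 228 without crl1 4 h repetition 1 and 2. Without wild type 2 h repetition 2 it was 495, and 363 of the 449 were among them.

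The response of wild type was asked next. By 2 h GH3.2 (LOC4326893), an enzyme that joins auxin to amino acids, rose by 4.46 ± 0.39 log2 units (21.9-fold, n = 2 arrays per group, adjusted p = 0.0083), from signals of 205 and 290 to 3748 and 7631. Of 25 Aux/IAA repressors, proteins that hold back auxin signalling, 18 lay above 0 (median 0.45, camera adjusted p = 5.5e-08; adjusted p = 0.17 with an estimated correlation). None passed over all probe sets, while adjusted over the list alone 10 rose and 1 fell. IAA10 (1.26 ± 0.24) and IAA15 (1.08 ± 0.21) were among the 10, as was IAA20 LOC4340245 (5.45 ± 0.72), which had an adjusted p of 0.1 over all probe sets. Of 8 GH3 genes 4 lay above 0 and 4 below (median 0.39, adjusted p = 0.001; adjusted p = 0.45 with an estimated correlation), 1 rose over all probe sets and 4 adjusted over the list alone. In the list of root and stem-cell regulators WOX6 (1.83 ± 0.23) and WOX11 (1.75 ± 0.26), a gene of crown root growth, rose adjusted over the list alone. Over all probe sets their adjusted p was 0.1 and 0.16, with both arrays at 2 h above both at 0 h. That list of 7 had 3 genes above 0, a median of -0.03 (0.08 after quantile normalization and -0.16 after centring) but a mean of 0.47, and camera called it up (adjusted p = 0.02; adjusted p = 0.66 with an estimated correlation). The genes of cytokinin synthesis and breakdown lay above 0 in 9 of 12 (median 0.12, and -0.00 after centring; adjusted p = 0.028; adjusted p = 0.66 with an estimated correlation; adjusted p = 0.054 with the GAPDH covariate). Without wild type 2 h repetition 2 its median was 0.35, and that of the root and stem-cell regulators -0.33. In this list 0 passed over all probe sets and 2 rose adjusted over the list alone, CKX4 (1.65 ± 0.35) and LOGL3 (1.38 ± 0.31).

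Growth groups lay higher at 2 h in wild type together with the array that stood apart. All 23 of 23 cytosolic ribosomal proteins (median 0.40, but 0.11 after quantile normalization; adjusted p = 1.3e-07; adjusted p = 0.66 with an estimated correlation) and 6 of 6 histones (0.53, but 0.32 after quantile normalization; adjusted p = 0.0018; adjusted p = 0.66 with an estimated correlation) lay above 0. No member passed over all probe sets or adjusted over the list alone. The expansins and xyloglucan endotransglucosylases lay above 0 in 19 of 25 (0.26, but 0.13 after centring; adjusted p = 0.0034; adjusted p = 0.72 with an estimated correlation), again with 0 members past in either way. Without wild type 2 h repetition 2, whose GAPDH ratio was 35.6, the adjusted p was 0.14 for ribosomal proteins (median 0.11), 0.22 for histones (0.12), 0.16 for root and stem-cell regulators and 0.99 for expansins (-0.05), whose direction then turned. Kinesins and the DREB list, which did not pass in the main fit, had medians of -0.31 and -0.86 without this array, in the other direction from the growth groups.

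In wild type 1 probe set, GH3.2, passed at 2 h, and 2 with repetition as a block, while 2538 had an unadjusted p under 0.05. The count was 0 without either wild type 0 h array, 2 without either crl1 0 h array, 3376 without wild type 2 h repetition 1, 0 without repetition 2 and 3 without either wild type 4 h array. GH3.2 missed the threshold without wild type 0 h repetition 1 (0.18) or 2 (0.087) and without wild type 2 h repetition 2 (0.064; log2 fold change 3.94). WOX9 was at -0.04 ± 0.56 (adjusted p = 0.99), RR1 at 0.29 ± 0.42 (0.88) and RR2 at -0.29 ± 0.31 (0.83). Centring each array on its median moved the median of all probe sets from -0.03 to -0.16 in wild type and from 0.05 to -0.15 in crl1 at 2 h, and changes at 2 h are read against these shifts.

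By 4 h in wild type GH3.2 was still 10.4-fold up (3.38 ± 0.39, n = 2 arrays per group, adjusted p = 0.026). CCA1 (LOC4344703), a morning gene of the circadian clock, fell by 1.65 ± 0.18 (adjusted p = 0.02). Both came with no overlap between the arrays of 4 h and 0 h. Of 7 clock genes 6 lay above 0 (median 0.73, adjusted p = 0.04; adjusted p = 0.66 with an estimated correlation; adjusted p = 0.087 after quantile normalization and 0.059 with the GAPDH covariate). Over all probe sets only CCA1 of these passed, and adjusted over the list alone GI (1.24 ± 0.27), PRR1 (1.69 ± 0.45) and PRR95 (0.73 ± 0.29) rose and CCA1 fell. The type-A cytokinin response regulators lay below 0 in 5 of 5 (median -0.61, adjusted p = 0.006; adjusted p = 0.66 with an estimated correlation), with 0 past over all probe sets and 0 adjusted over the list alone. Cytosolic ribosomal proteins lay above 0 in 22 of 23 (0.34, but 0.06 after quantile normalization; adjusted p = 5.2e-06; adjusted p = 0.66 with an estimated correlation), also with 0 members past in either way. Of the DREB and late embryogenesis proteins, genes of drought and cold, 10 of 12 lay below 0 (-0.76, 0.015; adjusted p = 0.66 with an estimated correlation). With the GAPDH covariate this call was lost (-0.65, adjusted p = 0.18). Adjusted over the list alone DREB1G fell (-2.82 ± 0.65, at or below background at 4 h, so the fold cannot be read as a bound). Homeodomain-leucine zipper factors lay below 0 in 21 of 25 (-0.18, and -0.29 after centring; adjusted p = 0.022; adjusted p = 0.66 with an estimated correlation; adjusted p = 0.12 with the GAPDH covariate), none past in either way.

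A total of 6 probe sets passed at 4 h in wild type, 4 up and 2 down, and 44 with repetition as a block (22 up, 22 down). The share up was 66.7%, 55.6% of 9 after quantile normalization and 30.8% of 13 after centring. The others were LOC4324218 (5.28 ± 0.45) and LOC4345848 (2.36 ± 0.28) up, LOC4332570 (1.94 ± 0.25) up and LOC4327187 down (-3.15 ± 0.28), chosen after their values were seen. WOX11 was at -0.91 ± 0.26 (adjusted p = 0.44), WOX9 at 0.31 ± 0.56 (0.97), RR1 at -0.99 ± 0.42 (0.68) and RR2 at -0.75 ± 0.31 (0.68). Leaving out either wild type 0 h array gave 1, either crl1 0 h array 2, and wild type 2 h repetition 1 or 2 gave 51 or 55. Without either crl1 2 h array it was 2, without wild type 4 h repetition 1 it was 0 and without either crl1 4 h array 2. GH3.2 and CCA1 passed in 3 and 2 of the 12 fits with 1 array left out, and the highest adjusted p of each was 0.43, without wild type 0 h repetition 1.

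The same response was asked of crl1. By 2 h IAA20 LOC4340245 rose by 5.85 ± 0.72 log2 units (57.6-fold, n = 2 arrays per group, adjusted p = 0.022), GH3.2 by 4.56 ± 0.39 (0.0033), WOX6 (LOC4332705) by 2.98 ± 0.23 (7.89-fold, 0.0022) and WOX11 (LOC4344325) by 2.44 ± 0.26 (5.41-fold, 0.011). GH3-8 (LOC4343785, 2.19 ± 0.24, 0.011), GH3.4 (LOC4339234, 1.70 ± 0.23, 0.036) and NAC067 (LOC4342753, a NAC factor, 2.08 ± 0.25, 0.019) rose as well, each with both arrays at 2 h above both at 0 h. Of 25 Aux/IAA repressors 20 lay above 0 (median 0.58, adjusted p = 6.1e-11; adjusted p = 0.11 with an estimated correlation), 1 rose over all probe sets, and adjusted over the list alone 14 rose and 1 fell. All 8 of 8 GH3 genes lay above 0 (1.09, 6.1e-11; adjusted p = 0.081 with an estimated correlation), 3 past over all probe sets and 4 adjusted over the list alone. Auxin response factors lay above 0 in 12 of 16 (0.27, 0.00042; adjusted p = 0.58 with an estimated correlation). ARF15 (0.87 ± 0.17), ARF1 LOC4350610 (1.22 ± 0.28) and ARF16 (0.81 ± 0.25) rose adjusted over the list alone and 0 did over all probe sets. Of the root and stem-cell regulators 4 of 7 lay above 0 (0.52, 0.00086; adjusted p = 0.53 with an estimated correlation), with WOX6 and WOX11 up in either way of adjusting, over all probe sets or adjusted over the list alone. After centring the medians were 0.38 for Aux/IAA repressors, 0.06 for auxin response factors and 0.31 for root and stem-cell regulators, the last at 0.34 after quantile normalization.

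**Figure D3:**
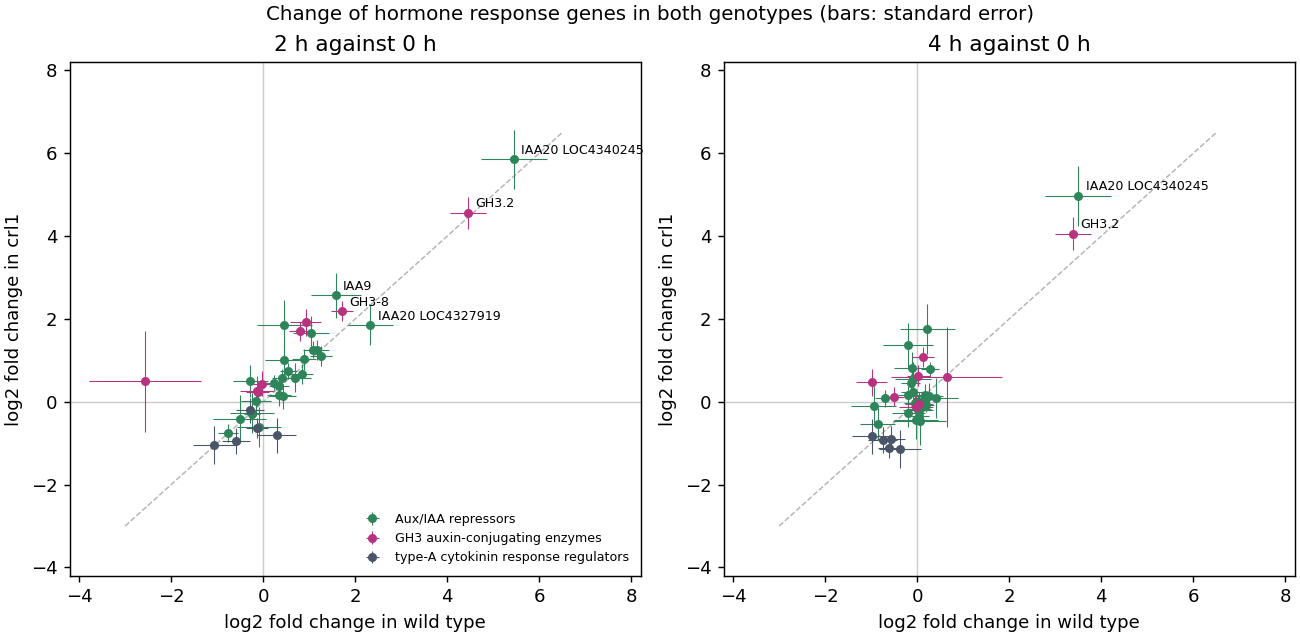
Log2 fold change against 0 h in wild type (horizontal) and in crl1 (vertical) at 2 h and 4 h, 1 point per gene of the Aux/IAA, GH3 and type-A response regulator lists, with bars of 1 SE and a dashed line of equal change. IAA20 LOC4340245 and GH3.2 lie far up in both genotypes, at 5.45 and 5.85 and at 4.46 and 4.56 at 2 h, and the type-A regulators lie below 0 in both genotypes at 4 h.

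Cytokinin groups moved in crl1 at 2 h too. Type-A response regulators lay below 0 in 5 of 5 (median -0.81, adjusted p = 0.00054; adjusted p = 0.66 with an estimated correlation), with 0 past over all probe sets and 0 adjusted over the list alone. Genes of cytokinin synthesis and breakdown lay above 0 in 8 of 12 (0.18, but -0.03 after centring; adjusted p = 0.006; adjusted p = 0.66 with an estimated correlation). CKX4 (1.93 ± 0.35), LOGL3 (1.60 ± 0.31) and LOGL5 (1.41 ± 0.35) rose adjusted over the list alone. Homeodomain-leucine zipper factors lay above 0 in 20 of 25 (0.34, 6.9e-05; adjusted p = 0.53 with an estimated correlation). HOX1 (1.20 ± 0.22) and HOX24 (2.70 ± 0.57, at or below background at 0 h, so the fold cannot be read as a bound) rose adjusted over the list alone. Primary-wall cellulose synthases lay above 0 in 5 of 6 (0.45, 0.034; adjusted p = 0.66 with an estimated correlation) and without wild type 2 h repetition 2 were at 0.05. Cell cycle genes lay below 0 in 30 of 40 (-0.19, 0.0033; adjusted p = 0.66 with an estimated correlation), and no cellulose synthase or cell cycle gene passed in either way. Centring gave medians of 0.14 for the homeodomain-leucine zipper factors, 0.24 for the cellulose synthases and -0.40 for the cell cycle.

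In crl1 at 2 h 13 probe sets passed (1 of no single gene, the others of 12 genes), 13 up and 0 down, with 43 under the block (42 up, 1 down) and 2 after centring; 1659 had an unadjusted p under 0.05. WOX9 was at 0.52 ± 0.56, RR1 at -0.81 ± 0.42 and RR2 at -0.21 ± 0.31, each with an adjusted p of 1. The count was 7 and 8 without crl1 0 h repetition 1 and 2, 29 without either wild type 2 h array, and 0 and 1 without crl1 2 h repetition 1 and 2. Without crl1 2 h repetition 1 and 2 the adjusted p was 0.051 and 0.092 for GH3.2, 0.2 and 0.22 for IAA20 LOC4340245, and 0.12 and 0.13 for WOX11. It was 0.14 and 0.13 for GH3-8, 0.16 and 0.23 for NAC067 and 0.44 and 0.24 for GH3.4. WOX6 was at 0.051 without crl1 2 h repetition 1. Without crl1 0 h repetition 1 and 2 the adjusted p was 0.12 and 0.17 for IAA20 LOC4340245, 0.071 and 0.091 for WOX11, 0.092 and 0.054 for GH3-8, 0.14 and 0.099 for NAC067 and 0.093 and 0.2 for GH3.4. The last passed in 2 of the 12 fits.

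By 4 h in crl1 GH3.2 was up 16.7-fold (4.06 ± 0.39, n = 2 arrays per group, adjusted p = 0.011) and CCA1 fell by 1.71 ± 0.18 (adjusted p = 0.014), with no overlap between the arrays of 4 h and 0 h. Type-A cytokinin response regulators lay below 0 in 5 of 5 (median -0.93, adjusted p = 4.7e-06; adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone 4 of them fell, among them RR4 (-1.11 ± 0.24) and RR2 (-0.93 ± 0.31), and 0 over all probe sets. GH3 genes lay above 0 in 6 of 8 (0.53, 0.0063; adjusted p = 0.53 with an estimated correlation), 1 up over all probe sets and 2 adjusted over the list alone, with GH3-8 at 1.07 ± 0.24. Genes of cytokinin synthesis and breakdown lay below 0 in 8 of 12 (-0.28, 0.011; adjusted p = 0.66 with an estimated correlation), CKX5 (-1.45 ± 0.32) and LOGL3 (-1.38 ± 0.31) down adjusted over the list alone. Photosynthesis genes did in 6 of 7 (-0.41, 0.00018; adjusted p = 0.66 with an estimated correlation), PSB28 (-0.92 ± 0.21) and PSAG (-1.06 ± 0.31), both of the photosystems, down adjusted over the list alone. Iron and zinc uptake genes did in 22 of 33 (-0.15, 0.008; adjusted p = 0.66 with an estimated correlation), with NRAMP3 (-0.85 ± 0.21) and NAS1 (-2.35 ± 0.61) down adjusted over the list alone. Kinesins lay above 0 in 30 of 32 (0.45, 0.00021; adjusted p = 0.7 with an estimated correlation), none past in either way. The GAPDH covariate gave medians of 0.29 for kinesins and -0.10 for cytokinin synthesis and breakdown, and centring gave -0.28 for iron and zinc uptake.

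In crl1 at 4 h 5 probe sets passed, 1 up and 4 down, and 16 under the block (7 up, 9 down). The others were LOC4327187 (-2.89 ± 0.28) and LOC4326913, whose 2 probe sets changed by -2.96 ± 0.33 and -3.93 ± 0.42, chosen after their values were seen. WOX11 was at -0.05 ± 0.26 (adjusted p = 0.99), WOX9 at 1.12 ± 0.56 (0.83), RR1 at -0.83 ± 0.42 (0.83) and RR2 at -0.93 ± 0.31 (0.64) over all probe sets. The count was 1 and 9 without crl1 0 h repetition 1 and 2, 8 and 10 without wild type 2 h repetition 1 and 2, and 0 without either crl1 4 h array. GH3.2 was at 0.13 without crl1 0 h repetition 1 or either crl1 4 h array, and CCA1 at 0.13 and 0.079 without crl1 0 h repetition 1 and 2 and at 0.13 and 0.15 without crl1 4 h repetition 1 and 2.

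Whether crl1 responded differently from wild type was asked with the difference of the responses, crl1 minus wild type. At 2 h all 8 of 8 GH3 genes (median 0.46, adjusted p = 0.012; adjusted p = 0.53 with an estimated correlation) and 15 of 16 auxin response factors (0.28, 0.012; adjusted p = 0.66 with an estimated correlation) responded higher in crl1. Changes lay lower in crl1 for 23 of 23 cytosolic ribosomal proteins (-0.50, but -0.23 after quantile normalization; adjusted p = 2.2e-08; adjusted p = 0.66 with an estimated correlation) and 6 of 6 histones (-0.75, 0.00016; adjusted p = 0.66 with an estimated correlation). They lay lower also for 29 of 40 cell cycle genes (-0.25, and -0.41 after quantile normalization; adjusted p = 0.0098; adjusted p = 0.7 with an estimated correlation). Without wild type 2 h repetition 2, with its GAPDH ratio of 35.6, these 3 lists had medians of -0.15, -0.34 and -0.05, and the auxin response factors one of 0.53. The DREB list and homeodomain-leucine zipper factors, which did not pass in the main fit, had medians of 0.70 and 0.35 without this array. No member of the 5 lists that passed in the main fit did so over all probe sets or adjusted over the list alone. WOX11 was at 0.69 ± 0.37 (adjusted p = 0.87), WOX9 at 0.56 ± 0.79 (0.95), RR1 at -1.10 ± 0.59 (0.87) and RR2 at 0.08 ± 0.44 (0.99).

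At 4 h the responses lay higher in crl1 for 30 of 32 kinesins (median 0.66, adjusted p = 2.6e-06; adjusted p = 0.66 with an estimated correlation) and 16 of 16 auxin response factors (0.42, 0.0019; adjusted p = 0.66 with an estimated correlation). So they did for 6 of 6 primary-wall cellulose synthases (0.61, 0.016; adjusted p = 0.66 with an estimated correlation). The same held for 20 of 25 homeodomain-leucine zipper factors (0.33, 0.022; adjusted p = 0.66 with an estimated correlation) and 5 of 8 GH3 genes (0.62, 0.026; adjusted p = 0.65 with an estimated correlation). Root and stem-cell regulators lay higher in 6 of 7 (0.60, 0.034; adjusted p = 0.66 with an estimated correlation; adjusted p = 0.056 without wild type 2 h repetition 2 and 0.05 after quantile normalization, short of the threshold; adjusted p = 0.18 with the GAPDH covariate). Photosynthesis genes lay lower in 7 of 7 (-0.54, but -0.32 after quantile normalization; adjusted p = 0.00038; adjusted p = 0.66 with an estimated correlation). So did 22 of 23 ribosomal proteins (-0.14, but 0.10 after quantile normalization; adjusted p = 0.011; adjusted p = 0.77 with an estimated correlation). With the GAPDH covariate the homeodomain-leucine zipper list was lost (0.19, adjusted p = 0.12), and the medians were 0.34 for kinesins, 0.25 for auxin response factors and -0.35 for ribosomal proteins. Over all probe sets no member passed, and adjusted over the list alone WOX6 did (1.27 ± 0.33, 0.018) and no other. WOX11 was at 0.86 ± 0.37, WOX9 at 0.80 ± 0.79, RR1 at 0.15 ± 0.59 and RR2 at -0.18 ± 0.44, each with an adjusted p of 0.99.

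Of single probe sets, limma called 0 for the difference of responses at 2 h (1831 at an unadjusted p under 0.05, lowest adjusted p 0.868) and 0 at 4 h (1090, lowest 0.99). Without wild type 2 h repetition 1 the array that stood apart is alone in its group, so that fit cannot show a difference of responses apart from this array. In simulated data 19% of 4-fold and 2% of 2-fold differences at 2 h were recovered, so differences of this size between the responses were mostly not detectable with 12 arrays.

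How far both genotypes responded alike was measured across genes, with 200 probe sets chosen by the wild-type response in repetition 1 and both responses then taken from repetition 2. Across these genes, which are not independent replicates, the responses correlated with r = 0.657 at 2 h and r = 0.747 at 4 h, and across all 32524 probe sets with r = 0.125 and r = 0.209. With the repetitions exchanged r was 0.264 at 2 h, where the rank correlation turned to -0.157 from 0.576, and 0.669 at 4 h. At 4 h the chosen probe sets moved in the direction of the choice by a mean of 1.07 log2 units in wild type and 1.06 in crl1, in 178 and 169 of 200. The means were 1.06 and 0.61 with the repetitions exchanged. At 2 h they moved by 0.09 in wild type and 0.45 in crl1, in 105 and 128 of 200. Probe sets chosen by the response of crl1 in repetition 1 moved at 2 h by 0.86 in wild type and 0.86 in crl1, in 146 and 157 of 200. With the repetitions exchanged those means were 0.48 and 1.08. The wild-type response in repetition 2 at 2 h is that of the array that stood apart, so r = 0.657 and the wild-type means of 0.09 and 0.86 rest on it. For genes chosen by wild type, the choice rests on it once the repetitions are exchanged. Both responses came from the same repetition, so whatever a repetition shared stays in this measure.

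The remaining lists passed in no comparison under the model and scaling used throughout. Their lowest adjusted p were 0.27 for auxin transporters (5 genes measured), 0.1 for root tissue (4), 0.1 for secondary wall and lignin (18), 0.19 for shoot meristem and leaf primordia (15) and 0.12 for heat shock (42). Jasmonate and wounding genes (30) reached 0.052 over all times in crl1 against wild type, where 22 lay above 0. LOX3 and LOX1.1 (-2.31 ± 0.37, crl1 at or below background at 2 h) were lower over all probe sets, the latter not without wild type 0 h repetition 2 (0.056), crl1 0 h repetition 1 (0.052) or wild type 4 h repetition 1 (0.066). Adjusted over the list alone 6 were higher and 2 lower. WRKY factors (5) reached 0.17, phosphate and ammonium transporters (13) 0.052, diterpenoid phytoalexin synthesis (6) 0.2 and aquaporins (22) 0.052. With the GAPDH covariate aquaporins passed in 5 comparisons, heat shock in 3 and phosphate and ammonium transporters in 1, with adjusted p of at least 0.53 with an estimated correlation. With repetition as a block jasmonate and wounding genes passed over all times (0.046), and heat shock (0.046) and aquaporins (0.029) in wild type at 2 h. Phosphate and ammonium transporters passed in crl1 at 4 h after quantile normalization (0.025). Without these settings the adjusted p of the 4 was 0.73, 0.72, 0.66 and 0.66 with an estimated correlation.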

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

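Tests without the array of wild type 2 h repetition 2, the test of root tissue genes and the view of time of day were chosen only after the results were seen, and the GAPDH covariate was added after seeing the data.

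Ribosomal protein, histone and cell cycle genes were singled out because their responses differed between the genotypes at 2 h, with median differences of -0.50, -0.75 and -0.25 (crl1 minus wild type, log2; -0.23, -0.59 and -0.41 after quantile normalization), all lost with an estimated correlation (adjusted p = 0.66, 0.66 and 0.7). With the GAPDH 3' to 5' ratio of each array as a covariate the 3 differences of responses stayed, at medians of -0.55, -0.82 and -0.31 (camera adjusted p = 1.7e-13, 9.1e-06 and 0.0022 at the preset correlation, and 0.44, 0.61 and 0.61 with an estimated correlation). This cannot decide on RNA degradation, as the covariate could move this contrast little. On the log scale the mean ratio changed little from 0 to 2 h in either genotype. The ratios were 9.41 and 17.3, then 3.84 and 35.6 in wild type. In crl1 they were 3.08 and 8.72, then 5.18 and 7.54. With the covariate the genotype difference of ribosomal proteins and histones shrank at 2 h from -0.40 to -0.23 and from -0.64 to -0.42 and grew before auxin from 0.11 to 0.37 and from 0.12 to 0.42, so degradation as a cause, and a genotype effect on growth genes, stay open. Without the array of wild type 2 h repetition 2 the median of the cell cycle genes shrank to -0.05 (adjusted p = 0.3), as this array as a source would need. For ribosomal proteins and histones the medians shrank to -0.15 and -0.34 (adjusted p = 0.0087 and 0.019 at the preset correlation; adjusted p = 0.77 and 0.71 with an estimated correlation), so a difference of genotypes and this array cannot be told apart, since a single wild-type array at 2 h then remains.

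The 449 probe sets that differed between the genotypes over all times were weighed next. Of 100 splits of the arrays within times 1, the real split, gave as many. The highest other gave 8, or 1 among the 28 splits with both repetitions even on each side. This cannot decide on chance, as the arrays were split at each time separately. Arrays of the same genotype and repetition shared deviations across times (median r = 0.464 over bright probe sets). With such arrays kept together, too few splits are possible for a share under 0.05. No smaller share can come from 100 splits, and the other splits count genotype differences as spread, which lowers their own counts. Single probe sets are not covered by this test. In simulated data 10 of 143 calls for this comparison fell on unchanged probe sets. Noise there was drawn independently for each array, without deviations shared within a repetition and without an array that stood apart. The share in the real data may therefore be higher. RNA degradation stays open, as the GAPDH covariate cannot decide on it. With the covariate 376 of the 449 stayed past the threshold and 449 kept their sign. The median ratio of the fold change with it to that without was 0.951 (quartiles 0.887 to 1.02). But the 449 were chosen as past in the same arrays without the covariate, which favours a ratio near 1. Its slope also rests largely on the 2 arrays of wild type 2 h, with GAPDH ratios of 3.84 and 35.6. Fewer root cells in the stem base of crl1 and a genotype effect cannot be told apart, since the root tissue list had a median of 0.01 log2 units over only 4 measured genes that went both ways. The mutation itself and sequence differences between the lines under the probes stay open as untested.

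The rise of Aux/IAA and GH3 genes by 2 h was weighed because no arrays of plants kept without auxin were used. The array of wild type 2 h repetition 2 as a source is argued against for the Aux/IAA list, which had an adjusted p of 2.5e-08 in wild type without it (adjusted p = 0.41 with an estimated correlation, and 0.17 with all arrays). It is argued against for GH3.2 too, whose rise in wild type was 4.46 ± 0.39 with this array and 3.94 ± 0.40 without, while crl1, whose arrays are others, rose by 4.56 ± 0.39. The call of GH3.2 in wild type ended without this array (adjusted p = 0.064), with a smaller fold and 1 array fewer. Auxin and the time of day or handling cannot be told apart for this rise, since 0 arrays of plants kept to 2 h without auxin were analysed.

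Other lists were singled out because the responses of the genotypes differed by the test of the difference itself. At 2 h the median differences were 0.46 for GH3 genes and 0.28 for auxin response factors. At 4 h they were 0.62 for GH3 genes, 0.42 for auxin response factors, 0.60 for root and stem-cell regulators, 0.66 for kinesins, 0.61 for primary-wall cellulose synthases, 0.33 for homeodomain-leucine zipper factors, -0.54 for photosynthesis genes and -0.14 for ribosomal proteins, with 0.10 for the last after quantile normalization. All 13 differences were lost with an estimated correlation, with adjusted p from 0.53 to 0.77.

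Wild type 2 h repetition 2 was singled out by control probe sets outside those tested, whose signals lay outside those of the other 11 arrays, with a hybridisation control signal of 1404, a poly-A control signal of 388, a GAPDH 3' to 5' ratio of 35.6 and an 18S rRNA signal of 556.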

How the results depend on the processing

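Array weights, the GAPDH covariate, the block within genotypes, list tests without wild type 2 h repetition 2 and the averaged responses were chosen after seeing the data. Counts below are in the order crl1 against wild type at 0, 2 and 4 h and over all times, wild type at 2 and 4 h, crl1 at 2 and 4 h, and the responses at 2 and 4 h averaged over both genotypes; those not printed stayed within 1.5 times. The 88 results on named genes kept direction and side of the threshold in 525 of 652 values under other settings and fell short in 127, and kept both in 575 of 1056 with 1 array left out; 0 reversed. With repetition as a block 88 of 88 results on named genes and 51 of 52 list calls were the same. A gene counts here once for each comparison that named it. The block gave at least as many calls of probe sets as the main fit in every comparison, which favours this outcome. Array weights, the GAPDH covariate and the block within genotypes were not run for the results on named genes. With a replicate block the counts were 71 at 0 h and 1037 over all times for the genotypes, 2 and 44 in wild type, 43 and 16 in crl1 and 81 and 261 averaged, and with a block within each genotype 4, 78, 39, 57, 104 and 377 for the changes with time. A filter at the 75th percentile, which tests fewer probe sets, gave 16, 11, 9 and 296 for the genotypes, and no filter gave 17 at 4 h. Array weights gave 52, 12 and 99 for the genotypes at 0, 2 and 4 h, 108 for wild type at 4 h, 30 and 11 in crl1 and 26 and 283 averaged. Both arrays of a group got the same weight, 0.348 each for wild type 2 h. This setting therefore weighted groups and did not single out the array that stood apart. Fits of the compared groups alone, with fewer arrays, gave 2 and 43 for the genotypes at 2 and 4 h, 0 for wild type at 2 h, 8 and 1 in crl1 and 22 averaged at 2 h. The GAPDH covariate gave 94 for the genotypes at 4 h, 2 and 141 in wild type, 56 and 22 in crl1 and 129 and 463 averaged. Centring gave 13 for wild type at 4 h, 2 for crl1 at 2 h and 13 averaged at 2 h, and eBayes without a trend gave 242 over all times, 0 and 3 in wild type, 1 and 0 in crl1 and 13 and 23 averaged. A 2-fold minimum gave 263 over all times. The responses correlated across genes with 0.264 (2 h) and 0.669 (4 h) once the repetitions were exchanged, and with 0.807 (2 h) and 0.813 (4 h) under the 75th percentile filter. With an estimated correlation 0 of 52 list calls remained. With the GAPDH covariate 46 of the 52 remained, 6 were lost and 26 others passed, and without wild type 2 h repetition 2 42 remained and 12 others passed; with an estimated correlation 0 passed under either. The expansin list of wild type at 2 h reversed without wild type 2 h repetition 2 (adjusted p = 0.99) and the ribosomal list of the difference at 4 h after quantile normalization (0.84). Leaving out 1 array, where the lone array of a group is assumed to vary like the others, gave 0 to 50, 11 to 4761, 7 to 44 and 151 to 3675 for the genotypes, 0 to 3376 and 0 to 55 in wild type, 0 to 29 and 0 to 10 in crl1, 0 to 1022 and 0 to 0 for the differences of responses at 2 and 4 h, 11 to 1379 and 14 to 277 averaged, and 54 list calls without wild type 2 h repetition 2. In the fit without wild type 2 h repetition 1 the array that stood apart was alone in its group, and its distance from repetition 1 no longer counted as spread. The cause was not tested for any of these unless stated. Signal at or below background limits the folds of LOX3, PIN2, NAC076, CSLC3, EXPB18, IAMT1, MFT2, LOX1.1, HOX24, DREB1G and WOX9. The crl1 signals of AGGLUTININ at 2 h, 10.7 and 17.2, lay near the backgrounds of these arrays, 11.5 and 16.9, so the size of that fold is uncertain too. Alternatives for the level of CRL1 were not run.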

Other observations

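The responses averaged over both genotypes, and every list test on them, were added after seeing the data. These list tests were adjusted over the 28 lists at 2 h and 4 h alone, apart from the 280 tests above. Their adjusted p come from a smaller family and cannot be set beside those of the 280 tests.

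Averaged over wild type and crl1, Aux/IAA and GH3 genes were among those that rose by 2 h. Medians at 2 h were -0.14 for auxin transporters and 0.10 for auxin response factors. Of the genes that the rule named, CKX4, SWEET16, BHLH172, LOGL3, IAA1, IAA10, IAA15 and GH3.4 rose and TPP7 fell. None of them passed in every fit with 1 array left out. IAA20 LOC4340245 rose by 5.65 ± 0.51 log2 units (n = 4 arrays per time, limma adjusted p = 0.0015), GH3.2 by 4.51 ± 0.28 (0.00021), GH3-8 by 1.96 ± 0.17 (0.0012), WOX6 by 2.40 ± 0.16 (0.00028), WOX11 by 2.09 ± 0.18 (0.0012) and NAC067 by 1.69 ± 0.18 (0.0046). In each genotype both arrays at 2 h lay above both at 0 h, and each of these genes passed in 12 of the 12 fits with 1 array left out. Of 25 Aux/IAA repressors 4 rose over all probe sets, and adjusted over the list alone 15 rose and 1 fell (median 0.63, adjusted p = 2.1e-14; adjusted p = 0.017 with an estimated correlation). Of 8 GH3 genes 3 rose over all probe sets and 4 adjusted over the list alone (0.73, 5.7e-09; adjusted p = 0.017 with an estimated correlation). Type-A cytokinin response regulators had a median of -0.39 at 2 h (adjusted p = 0.0014; adjusted p = 0.49 with an estimated correlation), with 2 down adjusted over the list alone.

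By 4 h IAA20 LOC4340245 (4.23 ± 0.51, n = 4 arrays per time, adjusted p = 0.0091) and GH3.2 (3.72 ± 0.28, 0.00054) were still up, and the clock gene CCA1 fell by 1.68 ± 0.13 (0.00054). GH3.2 and CCA1 passed in every fit with 1 array left out. No other gene that the rule named at 4 h did. Among these HSF07 and PPT2 rose, and AOS3, EGY3, CKX5, CFBP1, AMT1-2, CEBIP, AMY1.5, MRS2-A, PSY2 and PSB28 fell. All 5 type-A regulators fell adjusted over the list alone and 0 over all probe sets (median -0.84, adjusted p = 5.4e-06; adjusted p = 0.24 with an estimated correlation). Of 7 clock genes 1 rose and 1 fell over all probe sets, and adjusted over the list alone 5 rose, GI (1.33 ± 0.19) among them, and 1 fell (0.77, 0.0081; adjusted p = 0.56 with an estimated correlation). IAA20 LOC4340245 missed the threshold without wild type 0 h repetition 1 (0.061) or crl1 4 h repetition 1 (0.063), and its wild-type arrays at 4 h read 652 and 85.4.

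At 2 h 41 probe sets passed, 40 up and 1 down, and 81 with repetition as a block; at 4 h 148 did, 57 up and 91 down, and 261 with the block. The share up at 4 h was 38.5%, and 14.8% of 135 after centring. The 18 splits of the arrays within genotypes were too few to give a share under 0.05. At 2 h 2 of them gave as many as the real 41, and the highest other, 127, came from the split of repetition 1 against repetition 2, which points to a structure of the samples by repetition. Among the 7 splits with both repetitions even on each side the highest other gave 0. At 4 h 1 split, the real one, gave 148, and the highest other gave 0. Without wild type 2 h repetition 1 the count at 2 h was 1379 and without repetition 2 it was 30, within which 26 of the 41 lay. It was 14 and 11 without wild type 0 h repetition 1 and 2, 23 and 15 without crl1 0 h repetition 1 and 2, 11 and 12 without crl1 2 h repetition 1 and 2 and 23 and 21 without crl1 4 h repetition 1 and 2. At 4 h the count was 17 and 30 without wild type 0 h repetition 1 and 2, 35 and 58 without crl1 0 h, 277 and 276 without wild type 2 h, 62 without either crl1 2 h array, 14 without wild type 4 h repetition 1, and 17 and 35 without crl1 4 h repetition 1 and 2.

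Deviations of arrays with the same repetition number from their group means correlated with a median of 0.213 between groups of the same genotype and 0.107 between groups of different genotypes over all kept probe sets, and with 0.464 and 0.193 over the bright ones alone, across probe sets that are not independent replicates.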
